A study of Mus musculus with 10 samples.

How the data were processed

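Total RNA of 10 cultures of mouse cells had been labelled with biotin and hybridised to Affymetrix oligonucleotide arrays, per the labels' protocols. The 6 arrays of embryonic fibroblasts (MEFs) crossed genotype (wild type, WT, or Med23 knockout, KO) with serum time (0, 30 or 90 min), and the 4 arrays of 10T1/2 cells crossed overexpression of MAL with knockdown of Med23. Groups were taken from the sample labels, and each condition had 1 array.

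The values deposited by the authors were log2 expression values, 1 per probe set and array, for 45101 probe sets. RMA and MAS5 are named as tools per the submitters' processing notes, without their roles or versions. Which of them made the values, and whether the arrays of the MEFs and of the 10T1/2 cells were normalized together, is not given in the sources used here. The scale was read from the values themselves, which ran from 1.85 to 14.7 with array medians from 3.64 to 3.93. Every value column was mapped to a sample. No pseudocount was needed, because the deposited values were already logarithms.

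Gene names came from the platform annotation, with symbols updated through Entrez identifiers to the RefSeq gene table of assembly GRCm38.p6, which was used for names and for the order of neighbouring genes only. Of the 45101 probe sets, 64 were array controls, 34945 had 1 gene symbol, 932 had several and were left out, and 9160 were unnamed. Of the probe sets with 1 symbol, 34741 were matched through the identifier. They stood for 18193 genes. Each gene was represented by the probe set with the highest mean over the 10 arrays. A gene entered a fit when its highest value on the arrays of that fit was above the median of all probe sets there, which was 3.90 in the MEFs and 3.67 in the 10T1/2 cells. This left 11933 and 12440 genes. An array gives no depth of reading, so the number of arrays limits the precision.

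The fits used limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the log2 values. In the MEFs, 1 additive model held genotype and serum time and left 2 residual degrees of freedom, with 4.18 prior degrees of freedom. In the 10T1/2 cells, 1 additive model held MAL and knockdown and left 1 residual degree of freedom, with 3.83 prior degrees of freedom. The residual of each model holds noise and any interaction of its factors. p-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes of a comparison, with a threshold of 0.05. Comparisons of single arrays were made from values only, counted at an absolute log2 difference of at least 1, with no p-value. The files used here give no call of detection above background, so levels below the median of all probe sets on their array were taken as open. Folds of named genes that rest on such levels are given as "at least", with those levels raised to the array median, while coefficients and SE are as measured. This bound was chosen after the data were seen.

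The design, the alternatives, the rule for named genes and 23 gene lists were fixed before the data were examined. For each fitted comparison the rule took the 8 largest positive and the 8 largest negative coefficients among the genes past the threshold with 1 sign in every pair of arrays. Where fewer than 8 passed, the largest coefficients with 1 sign in every pair were given as values. For comparisons without a test it took the 5 largest values in each direction. Clone, predicted-gene and EST names were skipped. Med23, Mrtfa (the gene of MAL), Srf, Elk1 and members of the lists were named as well, and which list members to print was chosen after their values were seen. The choice leaned toward members whose call held when a serum time was left out, so the share of lost calls is given over all called list members and not only over those named.

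The lists covered smooth muscle contractile genes, actin-MAL-SRF target genes, immediate-early transcription factor genes, delayed serum response genes, SRF and its cofactors, adipocyte genes, fibroblast extracellular matrix genes, Mediator subunit genes other than Med23, S phase and mitosis genes, interferon-stimulated genes, cholesterol synthesis genes, p53 pathway genes, ER stress and ATF4 genes, TGF-beta and Notch target genes, Hox genes, and X- and Y-linked sex marker genes. They also covered skeletal muscle, bone and cartilage, endothelial, macrophage, epithelial, neural and neural crest, and ribosomal protein genes. Of their 539 entries, 496 had a named probe set and 43 were not analysed here. Each list with at least 3 tested genes was tested with camera, which compares the list with all other genes, at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists of a comparison. In the second version camera has only the residual degrees of freedom of the fit. These were 2 in the MEFs, 1 in the 10T1/2 cells and 3 in the fit over all 10 arrays. A list can hardly pass with so few, so failing that version says little about the list. The smooth muscle list failed it for KO against WT although its estimated correlation was -0.0256, below the preset 0.01. Other lists had estimates far above 0.01 in the MEFs. These were 0.645 for ribosomal protein, 0.428 for S phase and mitosis, 0.372 for immediate-early and 0.212 for cholesterol synthesis genes. The estimates are rough with so few degrees of freedom. Where the true correlation is above 0.01, the p-values at the preset correlation are too small. For comparisons of single arrays, a list's median was placed among 10000 random lists of its size matched on mean expression.

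The fits were tested on simulated values with genes of known change. The noise and the other coefficients of these values were taken from fits to the arrays. Of 100 genes changed by 2 on the log2 scale, 99 were recovered for KO against WT, 94 and 93 for serum at 30 and 90 min, 69 for MAL and 73 for the knockdown. Of 100 genes changed by 1, the fits recovered 78, 34, 23, 2 and 0 in that order. They made 9, 4, 3, 5 and 6 false calls. All other genes were unchanged in the simulation. Recovery can differ in comparisons where many more genes change, such as KO against WT.

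The alternatives were the mean of all probe sets of a gene, no filter on dim genes, a filter at the 75th percentile, quantile normalization of the filtered genes, centring of the arrays on their medians, an intensity trend in eBayes, 1 fit over all 10 arrays, fits without the term for the other factor, fits without the arrays of 1 serum time, an added bound of 1 on the absolute log2 change, and a bound of 1.5-fold for values without a test. Fits without probe sets whose names end in _s_at or _x_at, which can match several transcripts, were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the values and drew the figures.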

Results

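Gene expression was measured on 10 oligonucleotide arrays of cultured mouse cells, in a series that asked what Med23 does in cells turning toward smooth muscle or fat. Med23 encodes a subunit of Mediator, the complex that links transcription factors to RNA polymerase II. Embryonic fibroblasts (MEFs) from day 9.5 embryos, which had immortalised spontaneously in culture, gave 6 arrays, with wild-type (WT) and Med23 knockout (KO) cells each taken without serum (0 min) and after 30 and 90 min of serum. The serum series addressed genes that depend on SRF, a transcription factor of the serum response and of muscle genes. Another 4 arrays came from 10T1/2 cells, a mouse embryonic line that can form several mesenchymal cell types. They held an untreated control, overexpression of MAL, knockdown of Med23, and both treatments. MAL is a coactivator of SRF that responds to free actin, and its gene is Mrtfa. Each condition had 1 array, so there were no replicates, and the number of arrays limits the precision of every value. Pairs of arrays that differed in 1 factor took the place of replicates, and the labels tell of no further line of either genotype. The p-values rest on the residual spread over all arrays of a fit. That spread was drawn toward the spread of all genes, with 4.18 prior degrees of freedom in the MEFs and 3.83 in the 10T1/2 cells. It does not cover the spread between replicates of a condition or between further lines. The log2 values ran from 1.85 to 14.7, with array medians from 3.86 to 3.93 in the MEFs and from 3.64 to 3.70 in the 10T1/2 cells.

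Med23 itself (probe set 1452064_at) stood at 7.14, 7.39 and 6.90 in WT MEFs at 0, 30 and 90 min, and at 3.30, 3.30 and 2.91 in KO MEFs, below the array medians. The means were 7.14 ± 0.25 and 3.17 ± 0.23 (SD, n = 3 arrays). The KO coefficient was -3.97 (SE 0.13, n = 3 pairs, at least 9.54-fold lower, adjusted p = 9.28e-06). In 10T1/2 cells Med23 read 5.45 in the control, 5.67 with MAL, 4.24 with the knockdown and 3.94 with both treatments. The knockdown coefficient was -1.47 (SE 0.22, n = 2 pairs, 2.77-fold lower) and did not pass the test (adjusted p = 0.0689). Mrtfa (1434900_at) read 8.65 in the control, 8.33 with MAL, 8.54 with the knockdown and 8.44 with both treatments. Whether this probe set lies within the overexpressed sequence is not given in the sources used here, so it does not check the MAL label. Srf (1418255_s_at) read 8.08, 8.11, 7.95 and 7.77 on the same 4 arrays.

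**Figure D1:**
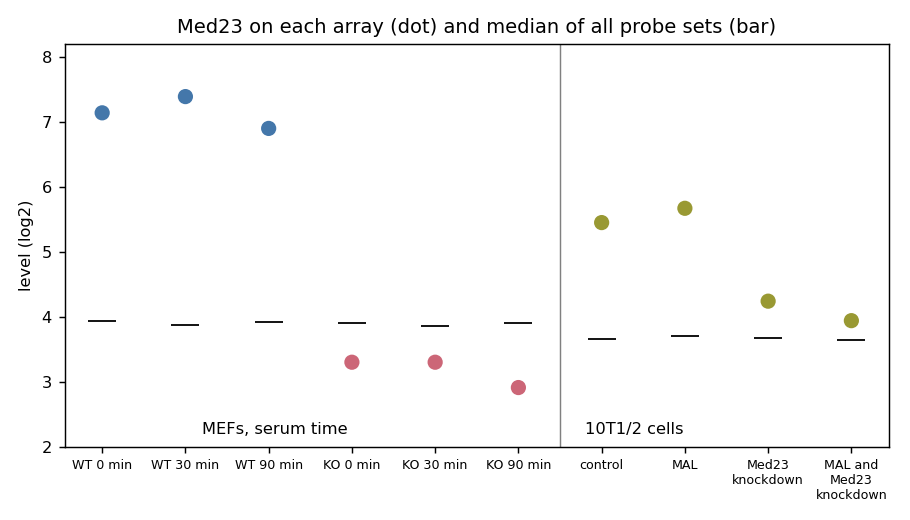
Level of Med23 on each of the 10 arrays (dots, log2) with the median of all probe sets on that array (bars), 1 array per condition. The 3 KO arrays lie between 2.91 and 3.30, below their array medians, and the arrays with the knockdown read 4.24 and 3.94 against 5.45 in the control.

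The comparison of KO with WT asked what the absence of Med23 goes with in the MEFs. Peg3, an imprinted zinc finger gene, rose from a mean of 3.34 to 12.34 (probe set 1417355_at, coefficient 9.0, SE 0.13, n = 3 pairs, at least 345-fold, adjusted p = 3.19e-06). Ptn, which encodes the heparin-binding growth factor pleiotrophin, rose at least 210-fold (8.49, SE 0.18, adjusted p = 3.19e-06), and Sfrp2, a secreted modulator of Wnt signalling, rose at least 173-fold (8.31, SE 0.16). Dcn, the small proteoglycan decorin of the extracellular matrix, fell from 13.64 to 4.51 (1449368_at, -9.14, SE 0.14, 563-fold, adjusted p = 3.19e-06). Mt1, a metallothionein, fell at least 276-fold (-8.61, SE 0.23, adjusted p = 5.25e-06). Further increases among the 8 genes with the highest coefficients were 8.17 for Cthrc1, 7.33 for Abi3bp, 7.26 for the transcription factor Zic1, 6.93 for the membrane protease Mme and 6.87 for the basement membrane protein Nid1. Further decreases were -7.77 for Cdkn2a, -7.53 for the chemokine Cxcl5, -7.07 for the cytochrome Cyp1b1, -6.71 for the extracellular superoxide dismutase Sod3, -6.45 for Cxcl15 and -6.42 for the adhesion molecule Cadm1. All 16 genes had the same sign in all 3 pairs. For 13 of them the level lay below the array median on all 3 arrays of 1 genotype, and for Nid1 on 2 of the 3. With those levels raised to the array medians, the coefficients of the 14 lay between 6.14 and 8.43 for the genes that rose and between -8.11 and -5.47 for those that fell.

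Smooth muscle contractile genes stood higher in KO MEFs. Of the 17 measured, 12 rose and 0 fell, over all genes and also adjusted over the list alone, with a median of 1.70. Tagln, an actin-binding marker of smooth muscle, rose from 5.62 to 11.49 (5.86, SE 0.18, n = 3 pairs, 58.2-fold, adjusted p = 7.6e-06). The myosin light chain gene Myl9 rose by 4.84 (SE 0.18, 28.6-fold, adjusted p = 1.53e-05), and Acta2, smooth muscle alpha-actin, by 0.88 (SE 0.12, adjusted p = 0.00246). The calponin gene Cnn1 rose by 1.86 (SE 0.42, adjusted p = 0.0152), with adjusted p = 0.122 without the 30 min arrays and 0.098 without the 90 min arrays, and lay below the array medians on 4 of the 6 arrays. The list test gave adjusted p = 1.91e-05, and adjusted p = 0.508 with an estimated correlation. The actin-MAL-SRF target genes went both ways, with 11 of 30 higher and 8 lower, 12 and 8 adjusted over the list alone, a median of 0.23 and adjusted p = 0.732 for the list. Among them the adhesion protein gene Vcl rose by 1.03 (SE 0.16, adjusted p = 0.0035) and the stretch-responsive repressor gene Ankrd1 fell by 3.70 on the log2 scale (SE 0.36, adjusted p = 0.000602). Hbegf, a ligand of the EGF receptor, fell by 3.88 on the log2 scale (SE 0.63, adjusted p = 0.00448), with adjusted p = 0.0564 without the 30 min arrays. Srf rose by 0.61 (SE 0.14, adjusted p = 0.0159), with adjusted p = 0.108 without the 0 min arrays and 0.0513 without the 30 min arrays. Its partner Elk1 fell by 0.58 on the log2 scale (SE 0.17, adjusted p = 0.0343), with adjusted p = 0.216 and 0.18 in the same order. Mrtfa had a coefficient of 0.45 and did not pass (adjusted p = 0.0607). Of 7 genes for SRF and its cofactors, 2 rose and 1 fell, 3 and 1 adjusted over the list alone, with a median of 0.12 and adjusted p = 0.764 for the list.

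Among 26 immediate-early transcription factor genes, which serum switches on within minutes, 3 rose and 8 fell with the KO over the 3 times, the same numbers adjusted over the list alone, with a median of -0.68 and adjusted p = 0.262 for the list. By serum time the median difference was -1.18 at 0 min, -0.495 at 30 min and 0.13 at 90 min. Ier3 fell by 1.71 on the log2 scale (SE 0.27, n = 3 pairs, adjusted p = 0.00374). Egr1 fell by 2.59 on the log2 scale (SE 0.49, adjusted p = 0.00801), with differences of -3.38, -0.90 and -3.48 at 0, 30 and 90 min, and with adjusted p = 0.0517 without the 0 min arrays and 0.0768 without the 90 min arrays. Fos rose by 1.10 (SE 0.25, adjusted p = 0.015), with adjusted p = 0.069 without the 30 min arrays, and Klf6 by 1.60 (SE 0.31, adjusted p = 0.00836), with 0.0549 in the same run. Delayed serum response genes were lower, with 1 of 36 up and 17 down by either adjustment and a median of -1.01. Ccnd1, the cyclin that drives entry into the cell cycle, fell by 2.41 on the log2 scale (SE 0.17, adjusted p = 0.000185), and Has2, a hyaluronan synthase, was the 1 gene that rose (3.99, SE 0.27, adjusted p = 0.000142). The chemokine genes Cxcl1 and Ccl2 fell by 4.15 and 2.62 on the log2 scale (SE 0.73 and 0.65, adjusted p = 0.0059 and 0.0203), with adjusted p = 0.066 for Cxcl1 without the 90 min arrays and 0.0932 for Ccl2 without the 30 min arrays. The list test gave adjusted p = 0.00185, and adjusted p = 0.508 with an estimated correlation.

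Cholesterol synthesis genes rose almost throughout, 16 of 17 over all genes and 17 adjusted over the list alone, with 0 lower and a median of 1.44. Idi1, an isomerase of the isoprenoid pathway, rose by 2.66 (SE 0.16, n = 3 pairs, 6.34-fold, adjusted p = 8.29e-05), Hmgcs1 by 2.13 (SE 0.15, adjusted p = 0.00015) and Fdps by 1.84 (SE 0.13, adjusted p = 0.000181), while Cyp51 had a coefficient of 0.56 and did not pass over all genes (adjusted p = 0.0942). The list test gave adjusted p = 1.44e-07, and adjusted p = 0.508 with an estimated correlation. Ribosomal protein genes rose in 14 of 19, 17 adjusted over the list alone, with 0 lower and a median of 0.61, led by Rps6 (1.75, SE 0.13) and Rps18 (1.21, SE 0.13). Their list test gave adjusted p = 1.91e-05, and adjusted p = 0.658 with an estimated correlation. The poly-A spike-in controls also stood higher in KO MEFs at each time, with medians of 5.99, 6.58 and 6.10 at 0, 30 and 90 min against 5.87, 6.21 and 5.69 in WT MEFs. Adipocyte genes were divided, 6 of 19 up and 7 down by either adjustment, with a median of -0.20 and adjusted p = 0.84. The fatty acid carrier gene Fabp4 fell by 2.00 on the log2 scale (SE 0.27, adjusted p = 0.002), and Zfp423, a transcription factor of fat cell precursors, rose by 2.99 (SE 0.15, adjusted p = 3.99e-05). Fibroblast extracellular matrix genes moved in both directions by large amounts, 10 of 30 up and 14 down, 11 and 14 adjusted over the list alone, with a median of -0.31 and adjusted p = 0.764. The collagen gene Col1a2 (3.89, SE 0.15) and the elastic fibre gene Fbln5 (5.55, SE 0.12) were among those that rose, and the protease gene Mmp3 (-4.16, SE 0.12) fell along with Dcn.

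The TGF-beta and Notch target genes held 3 of 20 up and 8 down, 5 and 8 adjusted over the list alone, with a median of -0.46 and adjusted p = 0.447. Tgfbi, a secreted matrix protein gene, rose by 6.36 (SE 0.14, n = 3 pairs, adjusted p = 3.19e-06), and the gene of the growth factor itself, Tgfb1, fell by 3.82 on the log2 scale (SE 0.24, adjusted p = 0.000101). Interferon-stimulated genes held 10 of 23 up and 5 down, 12 and 5 adjusted over the list alone, with a median of 0.49 and adjusted p = 0.0643, with Rtp4 higher (3.94, SE 0.16). The chemokine gene Cxcl10 fell by 3.24 on the log2 scale (SE 0.66, adjusted p = 0.0101), with adjusted p = 0.0922 without the 30 min arrays and 0.0958 without the 90 min arrays. ER stress and ATF4 genes held 2 of 19 up and 9 down, 3 and 9 adjusted over the list alone, with a median of -0.34 and adjusted p = 0.154; Ddit4, an inhibitor of mTOR signalling, fell by 2.73 on the log2 scale (SE 0.27). Chac1 fell by 1.94 on the log2 scale (SE 0.54, adjusted p = 0.0305), with adjusted p = 0.151 without the 0 min arrays and 0.194 without the 30 min arrays, and Psat1, an enzyme of serine synthesis, rose by 0.76 (SE 0.12, adjusted p = 0.00437), with adjusted p = 0.0513 without the 0 min arrays. S phase and mitosis genes held 8 of 33 up and 6 down, 9 and 6 adjusted over the list alone, and Mediator subunit genes other than Med23 held 8 of 32 up and 8 down by either adjustment. Their medians of 0.02 and 0.01 turned negative after quantile normalization (-0.04 and -0.01), with adjusted p = 0.904 and 0.942. The cyclin gene Ccnb2 rose by 3.09 (SE 0.13) where the topoisomerase gene Top2a fell by 1.08 on the log2 scale (SE 0.15), the replication gene Mcm3 fell by 0.95 on the log2 scale (SE 0.16, adjusted p = 0.0584 without the 30 min arrays), and Med9 rose by 1.34 (SE 0.23) where Med29 fell by 1.08 on the log2 scale (SE 0.12).

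The p53 pathway genes held 2 of 17 up and 6 down by either adjustment, with a median of -0.27, a mean of -1.08 and adjusted p = 0.0633. Cdkn2a and Cdkn2b, neighbouring genes that encode cell-cycle inhibitors, fell at least 126-fold and 53.3-fold. Neither read above 3.59 on a KO array or below 9.34 on a WT array. The p53 target gene Perp fell by 2.29 on the log2 scale (SE 0.13, n = 3 pairs, adjusted p = 6.96e-05), and Mdm2 had a coefficient of -0.38 (adjusted p = 0.198). Cdkn1a, the cell-cycle inhibitor p21, fell by 0.56 on the log2 scale (SE 0.15, adjusted p = 0.0278), with adjusted p = 0.17, 0.051 and 0.0951 without the 0, 30 and 90 min arrays. Hox genes, which mark body position, rose in 6 of 12 and fell in 0 by either adjustment, with a median of 0.38, adjusted p = 0.033, and adjusted p = 0.657 with an estimated correlation. Hoxd8 rose by 4.02 (SE 0.18) and Hoxd9 by 3.43 (SE 0.32). The 3 measured X- and Y-linked sex marker genes all rose by either adjustment, with a median of 1.75, adjusted p = 0.0106, and adjusted p = 0.508 with an estimated correlation. They were the Y-linked genes Kdm5d (2.03, SE 0.12), Uty (1.75, SE 0.14) and Eif2s3y (1.45, SE 0.18), and the lowest Eif2s3y value of the 6 MEF arrays was 6.34.

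The lists of markers of other cell types held from 3 to 8 measured genes. Macrophage genes fell in 3 of 5 and rose in 0 by either adjustment, with a median of -1.08, adjusted p = 0.0495, adjusted p = 0.626 with an estimated correlation, and adjusted p = 0.0566 after quantile normalization. They were Cd14 (-2.68, SE 0.25, n = 3 pairs), Lgmn (-1.58, SE 0.13) and Cd68 (-1.08, SE 0.12). Neural and neural crest genes held 2 of 7 up and 2 down by either adjustment, with a median of -0.16 and adjusted p = 0.873; Sox2, a transcription factor of neural progenitors, fell by 5.53 on the log2 scale (SE 0.30), and the adhesion molecule gene Ncam1 rose by 0.89 (SE 0.12). Endothelial genes held 2 of 5 up and 1 down by either adjustment, with a median of 0.03 that became -0.01 after quantile normalization and adjusted p = 0.764. Emcn rose by 2.28 (SE 0.12) and Flt1 fell by 2.64 on the log2 scale (SE 0.28). Bone and cartilage genes held 1 of 8 up, Col11a1 (4.30, SE 0.18), and 1 down, Omd (-2.59, SE 0.12), by either adjustment, with a median of 0.08 and adjusted p = 0.942. Skeletal muscle genes (7) and epithelial genes (3) held 0 calls by either adjustment. Their medians were -0.07 and -0.12 with adjusted p = 0.966 and 0.902. For skeletal muscle genes the mean of 0.03 and the direction of the test were positive. Several of the list members named above also lay below the array medians on all 3 arrays of 1 genotype. With those levels raised to the medians, the coefficients were 6.01 for Tgfbi, -4.46 for Sox2, -3.88 for Mmp3, 2.24 for Zfp423, 1.29 for Emcn, -1.05 for Fabp4 and -0.34 for Cd68.

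Over all genes, limma called 5018 of 11933 for KO against WT (42.1%), 2535 higher and 2483 lower, and 1948 of them by at least 2-fold (992 higher, 956 lower). The sign was the same in all 3 pairs for 5013 of the 5018, and r across genes between the differences at any 2 times was 0.937, 0.862 and 0.871, where genes are not independent replicates. Without the arrays of 0, 30 or 90 min the counts were 2680, 2398 and 4891. Of the 223 members of the gene lists that were called, 103 lost the call in at least 1 of these runs, 72, 90 and 22 in that order. A fit without the term for serum time called 2857.

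**Figure D2:**
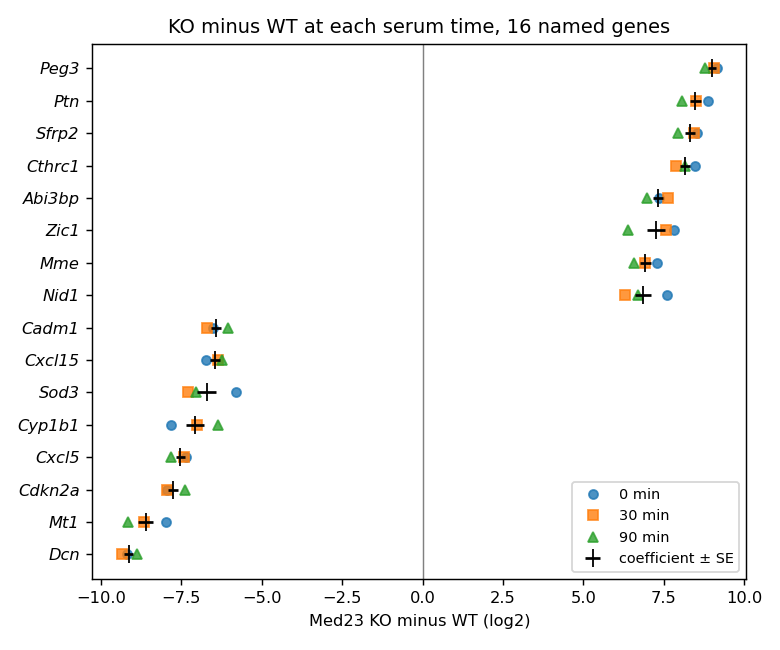
KO minus WT (log2) for the 16 genes with the largest coefficients, with 1 symbol per serum time and the coefficient with its SE in black. Each gene has the same sign at all 3 times, with coefficients from 6.87 to 9.0 for the genes that rose and from -9.14 to -6.42 for those that fell. For 13 of the 16 the lower genotype lies below the array medians on all 3 arrays.

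Serum at 30 min raised genes of the immediate-early class. Nr4a1, an orphan nuclear receptor gene, rose 127-fold (1416505_at, 6.99, SE 0.39, n = 2 pairs, adjusted p = 0.00333), Fosb rose at least 58.3-fold (6.50, SE 0.40, adjusted p = 0.00333), and Fos, a component of the AP-1 transcription factor, rose 80.2-fold (1423100_at, 6.33, SE 0.30, adjusted p = 0.00239). The remaining 5 of the 8 highest were Egr2 (6.10), the phosphatase gene Dusp5 (5.76), the transcription factor gene Atf3 (5.43), the antiproliferative gene Btg2 (5.29) and Zfp36, whose product destabilises mRNA (5.07). The coefficient of Egr2 was 5.93 with 1 of its levels at 0 min raised to the array median. Srf rose 7.16-fold (2.84, SE 0.17, adjusted p = 0.00333). The 2 genes that fell were Zkscan14 (-1.88) and Tmem186 (-1.70). Without the 90 min arrays these 2 had adjusted p = 0.113 and 0.136, Nr4a1 0.113, Egr2 0.134, Btg2 0.136 and Srf 0.0591. Others with negative values did not pass, such as Txnip (-2.26, adjusted p = 0.345), Pnrc2 (-2.03, adjusted p = 0.505), Gadd45a (-1.63, adjusted p = 0.632), Zfp551 (-1.50, adjusted p = 0.07), Arrdc3 (-1.45, adjusted p = 0.255) and Rasl11b (-1.38, adjusted p = 0.525).

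Of the 26 immediate-early genes, 10 rose at 30 min over all genes and 25 adjusted over the list alone, with a median of 3.56, adjusted p = 1.86e-42, and adjusted p = 0.305 with an estimated correlation. Junb rose by 4.53 (SE 0.15, n = 2 pairs, adjusted p = 0.000421) Ier2 by 4.57 (SE 0.28, adjusted p = 0.00333) and Nr4a2 by 1.86 (SE 0.18, adjusted p = 0.0261), while Egr1 had a coefficient of 4.88 and did not pass (SE 0.61, adjusted p = 0.0628). Without the 90 min arrays Ier2 had adjusted p = 0.0696 and Nr4a2 0.113. Delayed serum response genes rose in 4 of 36, 25 adjusted over the list alone, with a median of 1.57, adjusted p = 4.27e-28, and adjusted p = 0.134 with an estimated correlation. They included the cytokine gene Il6 (2.56, SE 0.29, adjusted p = 0.0471, or 1.98 with both levels at 0 min raised to the array medians) and the inhibitor gene Nfkbia (2.03, adjusted p = 0.0431), with adjusted p = 0.0591 and 0.225 without the 90 min arrays. All 30 actin-MAL-SRF target genes had positive coefficients, 2 of which passed over all genes and 11 adjusted over the list alone, with a median of 0.54, adjusted p = 5.15e-16, and adjusted p = 0.305 with an estimated correlation. The 2 were Srf and the matricellular gene Ccn1 (3.34, SE 0.30, adjusted p = 0.0228, or 0.208 without the 90 min arrays), while Vcl had a coefficient of 0.16. The smooth muscle list had 0 of 17 calls by either adjustment, a median of 0.34, adjusted p = 0.0142, and adjusted p = 0.345 with an estimated correlation. Smaller shifts past the list threshold were 0.43 for cholesterol synthesis genes (adjusted p = 1.98e-07), 0.19 for p53 pathway genes (0.0154), 0.19 for ER stress genes (0.0328), 0.17 for TGF-beta and Notch targets (0.0154), -0.23 for Hox genes (0.0267) and -0.12 for ribosomal protein genes (0.00871). With an estimated correlation these were at adjusted p = 0.345, 0.345, 0.437, 0.345, 0.494 and 0.702, and Hox genes were at adjusted p = 0.237 after quantile normalization. The p53 list shares Btg2, its 1 called gene, with the immediate-early list and Plk3 with the delayed list. The TGF-beta and Notch list shares Id1 and Id3 with the delayed list, so these shifts are not independent of the serum lists. The poly-A spike-in medians also stood higher at 30 min than at 0 min, at 6.21 against 5.87 in WT and 6.58 against 5.99 in KO MEFs. In all, limma called 30 of 11933 genes, 28 higher and 2 lower, with 954 at an unadjusted p under 0.05. Without the 90 min arrays 10 were called, 10 higher and 0 lower, 9 of them among the 30, and 10 of the 16 called list members lost the call.

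At 90 min of serum Fosl1, another AP-1 gene, rose at least 52.2-fold (1417487_at, 5.85, SE 0.54, n = 2 pairs, adjusted p = 0.00522), the cytokine gene Lif rose 47.5-fold (5.57, SE 0.58, adjusted p = 0.00611) and Nr4a1 44.3-fold (5.47, SE 0.39, adjusted p = 0.0047). Hbegf rose by 5.41, Dusp5 by 5.28, Noct by 5.15, Il6 by 4.97 and Hivep3 by 4.70. Txnip, an inhibitor of thioredoxin that also limits glucose uptake, fell 26.7-fold (1415996_at, -4.74, SE 0.56, adjusted p = 0.00807), and the cyclin gene Ccng2 fell 10.9-fold (-3.45, SE 0.18, adjusted p = 0.00196). Further decreases were -3.32 for Fam43a, -3.30 for the cell death gene Bmf, -3.28 for the PI3-kinase inhibitor gene Pik3ip1, -3.27 for Ttc30b, -2.68 for Zc3hav1l and -2.67 for Mterf2. With levels below the array medians raised to them, the coefficients were 5.31 for Hbegf, 4.40 for Il6, -3.07 for Bmf and -3.01 for Ttc30b. Srf stood 8.31-fold above 0 min (SE 0.17, adjusted p = 0.00196). Without the 30 min arrays Fosl1, Nr4a1, Hbegf, Hivep3, Txnip, Fam43a, Ttc30b, Zc3hav1l and Mterf2 lost the call, with adjusted p from 0.0509 to 0.0667.

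Delayed serum response genes rose in 25 of 36 at 90 min and in 29 adjusted over the list alone, with a median of 2.02, adjusted p = 1.12e-22, and adjusted p = 0.164 with an estimated correlation. Actin-MAL-SRF target genes rose in 19 of 30, 23 adjusted over the list alone, with a median of 0.99, adjusted p = 5.88e-19, and adjusted p = 0.305 with an estimated correlation. The integrin gene Itga5 rose by 2.43 (SE 0.25, n = 2 pairs, adjusted p = 0.00611), Ccn1 by 2.02 and Vcl by 2.00 (adjusted p = 0.0137 and 0.00571). Immediate-early genes rose in 19 of 26 and fell in 1, Klf2 (-1.03, adjusted p = 0.0374), or 22 and 1 adjusted over the list alone, with a median of 2.29, adjusted p = 1.34e-18, and adjusted p = 0.503 with an estimated correlation. S phase and mitosis genes fell in 13 of 33 and rose in 2, or 21 and 2 adjusted over the list alone, with a median of -0.82, adjusted p = 2.52e-05, and adjusted p = 0.608 with an estimated correlation. The mitotic kinase genes Aurka (-1.43, SE 0.32, adjusted p = 0.0361) and Cdk1 (-1.30, SE 0.22, adjusted p = 0.0177) fell, and Tyms, which makes thymidylate, rose by 1.58 (adjusted p = 0.0208), or by 0.85 with both levels at 0 min raised to the array medians. Cholesterol synthesis genes rose in 7 of 17, 9 adjusted over the list alone, with a median of 0.65, adjusted p = 7.92e-07, and adjusted p = 0.506 with an estimated correlation; Idi1 rose by 1.85 (SE 0.19) and Hmgcs1 by 1.49 (SE 0.18). Of the smooth muscle genes, 3 of 17 rose, and 4 adjusted over the list alone, with a median of 0.23, adjusted p = 0.000157, and adjusted p = 0.365 with an estimated correlation, Tagln by 0.91 (SE 0.22, adjusted p = 0.0439) and Smtn by 1.15 (adjusted p = 0.0399) among them. Of lists that did not pass, single members rose, such as Cdkn1a (1.65), Inhba (2.88), Skil (2.78), Flt1 (3.25) and Timp1 (2.04), or fell, such as Trp53inp1 (-1.95), Smad6 (-1.47) and the lipase gene Lipe (-2.06). Without the 30 min arrays the genes named here lost the call except Inhba, with adjusted p from 0.0509 for Ccn1 to 0.122 for Aurka.

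For 90 min of serum limma called 1612 of 11933 genes (13.5%), 544 higher and 1068 lower, and 822 by at least 2-fold. After quantile normalization it called 1330 genes, 646 higher and 684 lower, and without the 30 min arrays 18, 14 higher and 4 lower, all of which were among the 1612. In that run 102 of the 111 called list members lost the call. The median over all genes was -0.11 at 90 min. For lists that did not pass, the median, mean and test direction differed in sign at 30 min for adipocyte genes (-0.04, 0.03, down), S phase and mitosis genes (-0.06, 0.01, down), skeletal muscle genes (0.01, 0.00, down) and macrophage genes (-0.03, 0.04, up). At 90 min they differed for SRF and its cofactors (-0.17, 0.37, up), p53 pathway genes (-0.05, 0.36, up), Hox genes (-0.02, -0.13, up), bone and cartilage genes (0.00, 0.11, up) and macrophage genes (0.01, -0.08, up). Quantile normalization or centring changed the sign of the median of adipocyte, macrophage, extracellular matrix, interferon-stimulated and bone and cartilage genes at 30 min, and of p53 pathway, Hox, extracellular matrix and bone and cartilage genes at 90 min. Ribosomal protein genes at 90 min had a median of -0.22 with adjusted p = 0.192, and adjusted p = 0.0196 after quantile normalization.

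The response of KO cells was set against that of WT cells by values only, with 1 array per genotype and time and no replicate check. Egr3, an early growth response transcription factor gene, went from 3.15 to 11.13 at 30 min in KO cells and from 8.46 to 11.90 in WT cells, a difference of at least 3.78 in the response, since the level of 3.15 lay below the array median (4.54 as measured). Other measured differences at 30 min were 4.53 for Egr4, 4.36 for the chemokine gene Cxcl1, 3.75 for Rassf6 and 3.51 for the phosphatase gene Dusp1. Negative differences at 30 min were -3.53 for Cxcl10, -3.08 for Snai1, -2.66 for Lif, -2.62 for Traf1 and -2.43 for Socs3. Levels below the array medians leave the size open for Rassf6, Cxcl10 and Traf1. Immediate-early genes responded more in KO cells in 22 of 26, with a median difference of 0.72 above 100% of random lists at 30 min and 1.29 above 100% at 90 min. The random lists were not matched on the size of the serum response or on correlation between genes, so the percentiles only describe. Both times share the 0 min arrays, where the list stood lower in KO cells. Its median of KO minus WT was -1.18 at 0 min, -0.495 at 30 min and 0.13 at 90 min. For Egr3, Dusp1 and Jun the starting level was lower in KO cells, and the levels at 30 min were 11.13 and 11.90 for Egr3, 12.74 and 12.82 for Dusp1, and 11.02 and 11.39 for Jun in KO and WT cells. Egr1 read 9.81, 13.45 and 11.83 in WT cells and 6.43, 12.55 and 8.35 in KO cells. Fos read 5.99, 12.24 and 7.16 in WT cells and 6.63, 13.03 and 9.02 in KO cells.

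At 90 min the 5 highest measured differences were 4.63 for Egr3 (at least 3.87), 3.87 for Rassf6, 3.78 for Jun, 3.74 for the chemokine gene Ccl2 and 3.62 for the cell death gene Pmaip1. The 5 lowest were -4.73 for Ackr3, -3.78 for Mfsd13a, -3.69 for Ptx3, -3.32 for Cxcl10 and -3.09 for Zfp799. Levels below the array medians leave the size open for Rassf6, Ackr3, Cxcl10 and Zfp799. Median differences at 90 min were 0.51 for delayed serum response genes, 0.50 for S phase and mitosis genes and 0.54 for cholesterol synthesis genes, above 100%, 100% and 99.99% of random lists. The smooth muscle contractile genes had 0.16 at 30 min and 0.41 at 90 min, above 98.6% and 99.8% of random lists, and the actin-MAL-SRF target genes 0.03 and 0.20, above 76.1% and 93.9%. In all, 196 genes differed by at least 2-fold in the response at 30 min (103 higher and 93 lower in KO cells) and 768 at 90 min (398 higher and 370 lower). Across genes, which are not independent replicates, the responses of WT and KO cells correlated with r = 0.604 at 30 min and 0.657 at 90 min.

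**Figure D3:**
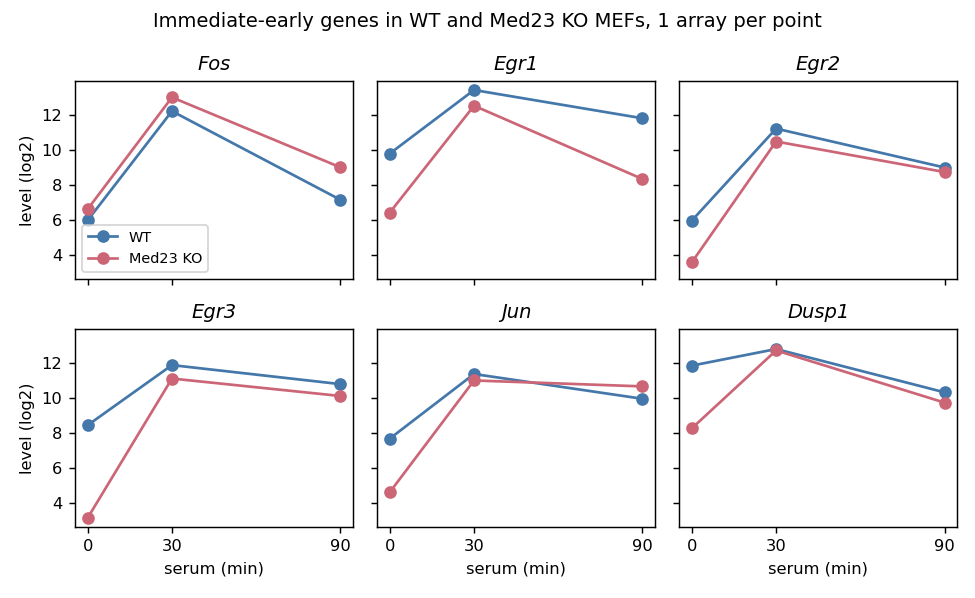
Levels (log2) of 6 immediate-early genes at 0, 30 and 90 min of serum in WT and KO MEFs, with 1 array per point. Egr3 starts at 3.15 in KO and 8.46 in WT cells and reaches 11.13 and 11.90 at 30 min, and Egr1 is lower in KO cells at each time.

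In 10T1/2 cells, MAL was compared over the pair without and the pair with the knockdown. With MAL Actg2, smooth muscle gamma-actin, rose 21.8-fold (1422340_a_at, 4.45, SE 0.19, n = 2 pairs, adjusted p = 0.0259) and Cnn1 21.5-fold (1417917_at, 4.43, SE 0.23, adjusted p = 0.0265). Tagln rose 10.8-fold (1423505_at, 3.44, SE 0.18, adjusted p = 0.0265), with levels of 6.64 in the control, 10.12 with MAL, 7.78 with the knockdown and 11.17 with both. Pkp2, a desmosome protein gene, rose by 4.42, the ubiquitin ligase gene Asb2 by 3.96, and Acta1, skeletal alpha-actin, by 3.24. The protease inhibitor gene Slpi and the alcohol dehydrogenase gene Adh1 fell by 3.39 and 2.90 on the log2 scale (adjusted p = 0.0339 and 0.0487). Further large coefficients did not pass: 3.6 for Pilra and 2.88 for Stbd1, and for the secreted or inflammatory genes Wfdc18 (-4.40), Hp (-4.12), Lcn2 (-3.71), Cxcl5 (-3.63) and Lbp (-3.42) and for Tmem176a (-3.71), with adjusted p from 0.0636 to 0.0858. With levels below the array medians raised to them, the coefficients were 3.86 for Pkp2, 3.85 for Asb2, 3.05 for Pilra and -3.28 for Lcn2.

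The smooth muscle list held 3 of 22 up and 0 down with MAL, 13 and 1 adjusted over the list alone, with a median of 0.78, adjusted p = 3.15e-08, and adjusted p = 0.842 with an estimated correlation. Members given as values are Myl9 at 2.36 (adjusted p = 0.0636), Lmod1 at 2.07 (0.0651) and Acta2 at 0.46 (0.188). Actin-MAL-SRF target genes held 1 of 31 up, 13 adjusted over the list alone, with 0 down, a median of 0.67, adjusted p = 1.09e-07, and adjusted p = 0.842 with an estimated correlation; Nexn stood at 2.13 and Fhl1 at 2.25 (adjusted p = 0.0651 for both). S phase and mitosis genes had a median of -0.60 with 0 of 33 calls, 1 up and 16 down adjusted over the list alone (adjusted p = 1.09e-07, and adjusted p = 0.842 with an estimated correlation), with Ccne2 at -2.23 (adjusted p = 0.0636) and the replication licensing gene Cdc6 at -1.61 (adjusted p = 0.0658). Adipocyte genes had a median of -0.33 with 0 of 24 calls, 0 up and 7 down adjusted over the list alone (adjusted p = 0.00777, and adjusted p = 0.842 with an estimated correlation). Their values were -2.55 for Zfp423, -2.04 for the preadipocyte gene Dlk1, -1.26 for Cebpa, -1.0 for Fabp4 and -0.46 for Pparg, the nuclear receptor of fat cell formation (adjusted p = 0.124, 0.0688, 0.0684, 0.0938 and 0.206). Extracellular matrix genes (-0.48, 0 up and 6 down of 31 adjusted over the list alone), bone and cartilage genes (-0.51, 0 up and 4 down of 8) and delayed serum response genes (-0.49, 2 up and 8 down of 37) had adjusted p = 0.000771, 0.00777 and 0.0177 for the list, and adjusted p = 0.854, 0.854 and 0.842 with an estimated correlation. Fmod, a matrix proteoglycan gene, stood at -2.73 (adjusted p = 0.0519), or -2.00 with both levels with MAL raised to the array medians. Median, mean and test direction differed in sign with MAL for interferon-stimulated (-0.02, -0.08, up), p53 pathway (-0.07, 0.06, down), ER stress (-0.03, -0.01, up), Hox (0.01, -0.12, down), macrophage (0.01, -0.23, down) and ribosomal protein genes (-0.02, 0.01, up), none of which passed, and quantile normalization turned the medians of Hox and ribosomal protein genes.

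For MAL limma called 8 of 12440 genes, 6 higher and 2 lower, with 3432 at an unadjusted p under 0.05. The count was 0 without the filter on dim genes, 0 with the arrays centred on their medians, 0 without a term for the knockdown, and 853 after quantile normalization (465 higher, 388 lower).

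**Figure D4:**
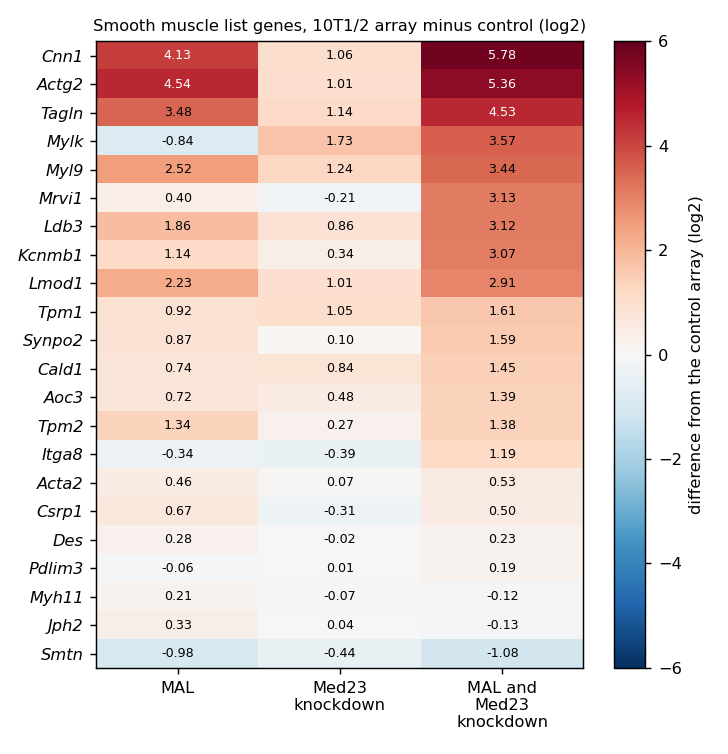
Difference from the control array (log2) for 22 smooth muscle contractile genes in 10T1/2 cells with MAL, with the Med23 knockdown and with both treatments, 1 array each. Cnn1 (5.78) and Actg2 (5.36) are the highest with both treatments, and Smtn is lower than in the control (-1.08).

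The comparison of knockdown with no knockdown in 10T1/2 cells gave 0 calls, so its genes are given as values. Abi3bp, an extracellular matrix gene, had a coefficient of 3.42 (SE 0.38, n = 2 pairs, at least 6.57-fold), Sfrp2 3.35, Epas1, a hypoxia-inducible transcription factor gene, 3.32, Rspo3, a Wnt agonist gene, 3.18 and Mylk, myosin light chain kinase, 3.07. Pawr and Tnfrsf21 (2.60 with 1 level raised to the array median) stood at 2.90 each and the matrix gene Thbs1 also at 2.90. Tgfbi was at -3.18 (SE 0.21, 9.03-fold), the growth factor gene Igf1 at -2.92, Il1rn at -2.85, Penk at -2.73, Ifi27l2a at -2.53, Wfdc3 at -2.43, Tspan15 at -2.41 and Serpinb1a at -2.33. The smallest adjusted p was 0.0689. Srf stood at -0.23 and Elk1 at -0.37.

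With the knockdown, smooth muscle contractile genes had a median of 0.68, with 0 of 22 calls over all genes, 9 up and 0 down adjusted over the list alone, adjusted p = 0.00416, and adjusted p = 0.937 with an estimated correlation. Their values included 1.36 for Cnn1, 1.10 for Tagln and 0.07 for Acta2. Actin-MAL-SRF target genes had a median of 0.38, with 0 of 31 calls, 9 up and 0 down adjusted over the list alone, adjusted p = 0.00416, and adjusted p = 0.937 with an estimated correlation, and Enah stood at 2.11. Cholesterol synthesis genes had a median of -0.52, with 0 of 17 calls, 0 up and 7 down adjusted over the list alone, adjusted p = 0.00873, and adjusted p = 0.937 with an estimated correlation, with Mvd at -1.55 and Fdps at -1.41. Of the 17, 11 were negative in both pairs of arrays, and for all 17 the difference was lower in the pair with MAL than in the pair without it. Immediate-early genes had a median of -0.46, with 0 of 25 calls, 3 up and 11 down adjusted over the list alone, adjusted p = 0.0396, and adjusted p = 0.937 with an estimated correlation, with Egr1 at -1.39 and Egr2 at -1.59 (adjusted p = 0.0689 for both). Adipocyte genes had a median of -0.16, 1 up and 1 down of 24 adjusted over the list alone, and did not pass (adjusted p = 0.328). Fabp4 read 3.30 in the control, 2.64 with MAL, 4.89 with the knockdown and 3.55 with both (below the array median on all but the knockdown array), Pparg 6.67, 6.35, 6.87 and 6.28, and Cebpa 7.66, 6.34, 7.19 and 5.99 on the same arrays. The Notch ligand gene Jag1 stood at 2.04. Interferon-stimulated genes had a median of -0.39 with adjusted p = 0.054, and adjusted p = 0.0449 after quantile normalization. The knockdown coefficient of Pparg was 0.07 and became -0.10 after quantile normalization. The median, mean and test direction differed in sign with the knockdown for extracellular matrix (0.05, 0.00, up), Mediator subunit (-0.10, 0.05, down), neural (-0.16, 0.07, down) and ribosomal protein genes (-0.06, 0.05, up), none of which passed.

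For the knockdown limma called 0 of 12440 genes, with 3972 at an unadjusted p under 0.05 and 394 higher and 89 lower by at least 2-fold in both pairs. Other runs called 340 genes with the mean of all probe sets, 899 after quantile normalization (602 higher, 297 lower), 599 with an intensity trend and 2658 in 1 fit over all 10 arrays.

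**Figure D5:**
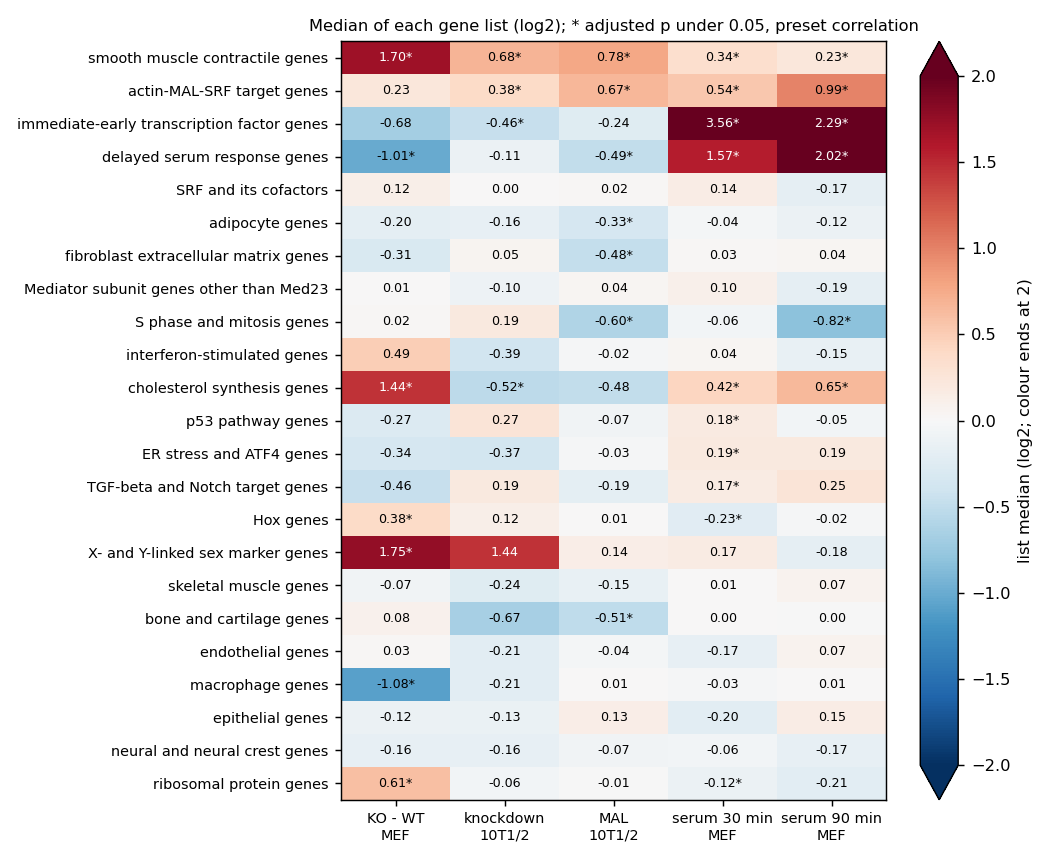
Median coefficient (log2) of each of the 23 gene lists in the 5 fitted comparisons, with an asterisk where the list test with the preset correlation passed. Smooth muscle contractile genes have medians of 1.70 with the KO, 0.78 with MAL and 0.68 with the knockdown, and with an estimated correlation 0 lists passed in any comparison. That version has 2 degrees of freedom in the MEFs and 1 in the 10T1/2 cells, so a list can hardly pass it.

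Each 10T1/2 treatment was also set against the control by values only, with 1 array each and no replicate check. With both treatments Cnn1 stood 5.78 above the control, Actg2 5.36, Pkp2 4.54, Tagln 4.53 and the immune receptor gene Pilra 4.15. The lowest were Wfdc18 at -5.30, Il1rn at -5.09, Igf1 at -5.07, Penk at -4.98 and Tgfbi at -4.75. With both treatments, smooth muscle contractile genes had a median of 1.52, above 100% of random lists, with 15 of 22 at least 2-fold higher and 1 lower, against 0.73 with MAL alone and 0.31 with the knockdown alone. Actin-MAL-SRF target genes had 0.91, with 15 of 31 at least 2-fold higher, against 0.48 and 0.32. Adipocyte genes had -0.62, above 0.32% of random lists, with 11 of 24 at least 2-fold lower and 1 higher, against -0.29 with MAL and -0.32 with the knockdown. Among them Dlk1 stood at -3.32, the triglyceride synthesis gene Dgat2 at -2.06, Cebpa at -1.67, Lipe at -1.63 and Fasn, fatty acid synthase, at -1.60. The counts of genes at least 2-fold apart from the control were 1047 with MAL, 948 with the knockdown and 3667 with both, the last 2231 higher and 1436 lower.

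With MAL alone the 5 highest were Pkp2 (4.63), Actg2 (4.54), Cnn1 (4.13), Asb2 (3.85) and Tagln (3.48), and the 5 lowest were Hp (-5.70), Wfdc18 (-5.39), Cxcl5 (-5.35), Lcn2 (-5.33) and Sfrp2 (-4.65). With the knockdown alone they were Abi3bp (2.67), Msrb3 (2.62), Npnt (2.59), Otor (2.53) and Rspo3 (2.52), and Tgfbi (-3.40), Wfdc3 (-3.33), Igf1 (-3.09), Penk (-3.05) and Dcn (-2.73). With levels below the array medians raised to them, the values were 3.91 for Pkp2, 3.75 for Asb2 and -4.47 for Lcn2 with MAL, 2.28 for Abi3bp with the knockdown, and 3.82 for Pkp2 and 3.99 for Pilra with both treatments. The poly-A spike-in controls had medians of 8.26 in the control, 7.61 with MAL, 7.68 with the knockdown and 6.97 with both treatments. Those of the hybridisation spike-in controls (bioB, bioC, bioD and cre) were 9.43, 9.21, 9.27 and 9.015. The mean correlation across probe sets with the 6 MEF arrays was 0.867, 0.883, 0.887 and 0.908 in the same order. Xist, which is expressed from the inactive X chromosome, read 10.04, 9.43, 10.73 and 11.62, with a knockdown coefficient of 1.44 (adjusted p = 0.0983), and Eif2s3y read at most 2.85 on these arrays.

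The sum of the single differences was set against the difference with both treatments, again with no replicate check. The largest positive departures were 3.46 for Myom1, a sarcomere gene that read 3.05, 3.27, 3.32 and 7.0 in the control, with MAL, with the knockdown and with both, then 3.44 for Cxcl5, 3.44 for Saa3, 3.37 for Sfrp2 and 3.24 for Lcn2. The largest negative departures were -3.69 for Serpinb1a, -2.50 for Omd, -2.32 for Aqp5, -2.01 for Itgbl1 and -1.98 for Tcim. Levels below the array medians leave the size open for Myom1, and the departure of Lcn2 was at least 2.38. In all, 893 genes departed by at least 2-fold, 669 upward and 224 downward. Smooth muscle contractile genes had a median departure of 0.07, above 96.4% of random lists, and actin-MAL-SRF target genes 0.07, above 99.4%. Cholesterol synthesis genes had -0.95, above 0% of random lists, with 17 of 17 negative, and adipocyte genes -0.18, above 16.4%.

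Loss of Med23 was compared between the MEFs and the 10T1/2 cells, which share no arrays. Across 11230 genes, which are not independent replicates, r between the KO and the knockdown coefficients was 0.149 and rho was 0.115, with r from 0.0815 to 0.168 when 1 pair of arrays of each system was used, and 54.5% of genes had the same sign. Genes at least 2-fold higher in both numbered 162, against 67.1 for independent lists, and 56 were lower in both, against 14.9. Opposite moves were seen in 29 genes higher in KO cells and lower with the knockdown, against 15.7, and in 63 genes the other way, against 63.6. Abi3bp (7.33 and 3.42), Rspo3 (3.95 and 3.18) and the natriuretic peptide receptor gene Npr3 (5.13 and 2.86) were higher in both, and Il1rn (-3.36 and -2.85) and Penk (-3.04 and -2.73) lower in both, in the order of KO and knockdown. The 2 systems differ in cell line, in serum and in the way Med23 was removed.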

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

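The tests reported here were chosen only after the result that they bear on had been seen, except the count after quantile normalization, which was fixed before the data were examined. KO coefficients in the MEFs and knockdown coefficients in the 10T1/2 cells were opposite for 13 named genes or list members, each picked out because both coefficients were at least 2-fold with 1 sign in every pair of arrays and their difference passed a limma contrast in 1 fit over all 10 arrays. The knockdown coefficients themselves did not pass. Tgfbi differed by 9.53 (6.36 with the KO and -3.18 with the knockdown, adjusted p = 1.85e-06), Serpinb1a by 5.47 (3.15 and -2.33, adjusted p = 0.00371), Ifi27l2a by 4.69 (2.17 and -2.53, adjusted p = 7.58e-05) and Wfdc3 by 4.18 (1.75 and -2.43, adjusted p = 0.000799). The cholesterol synthesis genes Mvd, Fdps, Lss, Mvk and Dhcr7 differed by 3.34, 3.25, 2.64, 2.49 and 2.34 (adjusted p = 0.000554, 0.000817, 0.00273, 0.00167 and 0.000432). In the other direction stood Cxcl5 at -9.32 (-7.53 and 1.79, adjusted p = 0.000252), Cyp1b1 at -8.20 (-7.07 and 1.13, adjusted p = 2.06e-05), Fabp4 at -3.25 (-2.00 and 1.25, adjusted p = 0.00137) and Tnfaip3 at -2.57 (-1.55 and 1.02, adjusted p = 0.0257). The knockdown coefficients of Cxcl5 and Serpinb1a came mostly from the pair of arrays with MAL, as their departures from additivity were 3.44 and -3.69. With levels below the array medians raised to them the differences were 9.18 for Tgfbi, 5.10 for Serpinb1a, 4.08 for Wfdc3, -8.60 for Cxcl5 and -7.54 for Cyp1b1. For Fabp4 the size stays open. Its sign in the pair with MAL stays open as well, since both levels of that pair lay below the array medians. Ankrd1 also passed the contrast (-4.85, adjusted p = 0.00372), but the knockdown pairs differed in sign (-0.13 without MAL and 2.44 with it).

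Of the gene lists, 7 differed between the 2 systems in the same contrast. The median differences were 2.14 for cholesterol synthesis genes (adjusted p = 3.43e-09), 0.84 for interferon-stimulated genes (0.0102), 0.80 for smooth muscle contractile genes (0.0144), 0.59 for ribosomal protein genes (0.00069), -0.80 for delayed serum response genes (0.0123), -0.83 for p53 pathway genes (0.00616) and -0.64 for TGF-beta and Notch target genes (0.0333). With an estimated correlation the same lists were at adjusted p = 0.486, 0.386, 0.386, 0.494, 0.386, 0.494 and 0.486. Smooth muscle contractile genes were higher in both systems (medians of 1.70 with the KO and 0.68 with the knockdown). For this list the systems differ in size and not in direction, and Med23 itself had coefficients of -3.97 and -1.47. Delayed serum response genes were lower with the KO (-1.01). With the knockdown their median of -0.11 lay close to that of all genes (-0.08), and the list did not pass (adjusted p = 0.606). The medians of the other lists had opposite signs, but with the knockdown only cholesterol synthesis genes passed the list test (adjusted p = 0.00873). Interferon-stimulated, p53 pathway, TGF-beta and Notch target and ribosomal protein genes had adjusted p = 0.054, 0.297, 0.184 and 0.692 there. For ribosomal protein genes the knockdown median of -0.06 stood beside a mean of 0.05. For all cholesterol synthesis genes the knockdown difference was lower beside MAL than without it. Dusp1 fell in WT cells and rose in KO cells between 0 and 90 min of serum (-1.53 and 1.47, a difference of 3), which was not tested.

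The breadth of the difference between KO and WT MEFs, 5018 of 11933 genes, was weighed against causes other than Med23. The 10 splits of the 6 arrays are too few for a share under 0.05, with 5018 genes for the real split, the 1 split to reach that number, and 0 as the highest of the others. For the genes called at 2-fold or more, gains and losses of chromosome segments are argued against as the whole cause. Of these genes, 82.0% (1594 of 1945 placed on the assembly) stayed 2-fold apart after the median of their 20 nearest genes was taken off. Over all placed genes that neighbour median had a median absolute size of 0.147. Called genes under 2-fold were not covered. Across genes the KO coefficient correlated with the neighbour median at r = 0.209, so a part from segments stays open. Other differences between the lines and in the RNA stay open: 69.9% of the 306 genes called at 2-fold or more with a 2-fold knockdown coefficient shared its sign, as did 65.4% of the 254 with a 2-fold MAL coefficient. In a joint regression across genes the slope of KO was 0.222 on the knockdown and 0.0283 on MAL, which correlate with r = 0.498, and KO arrays had higher poly-A spike-ins and a smaller difference between the transcript ends of the transferrin receptor (1.27, 1.39 and 1.35 against 1.49, 1.57 and 1.79), while that of pyruvate carboxylase (1.94, 2.26 and 1.68 against 2.05, 2.10 and 1.82), Gapdh (-0.20, -0.20 and -0.26 against -0.26, -0.16 and -0.16) and actin (0.16, 0.14 and -0.07 against 0.12, 0.02 and 0.15) changed direction between times. With 1 line named per genotype, the loss of Med23 and any other difference between the lines cannot be told apart, and the 3 Y-linked genes that rose stand beside it.

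The 10T1/2 arrays shifted in a graded way, with 1047, 948 and 3667 genes at least 2-fold from the control with MAL, with the knockdown and with both. RNA of the MEF lines in the array of both treatments is argued against, since 43.1% of the 2231 raised genes (962) lay above the control and above each MEF array, and Eif2s3y read at most 2.85 on the 10T1/2 arrays against at least 6.34 on the MEF arrays. The medians of the deposited 10T1/2 arrays lay between 3.64 and 3.70. Their upper quartiles were 6.38, 6.36, 6.5 and 6.59 in the control, with MAL, with the knockdown and with both. Such a difference in spread is argued against as the whole cause of the 3667, since quantile normalization removes it. After that step 3697 genes were still 2-fold apart with both treatments. With medians so close this count could change little, so it does not test how the arrays were scaled before deposit. In the same step the calls went from 8 to 853 for MAL and from 0 to 899 for the knockdown. The amount or quality of the RNA stays open, because the poly-A spike-ins stood at -1.29 with both treatments relative to the control, while the difference between the ends of the transcript ranged over the 4 arrays by 0.13 for Gapdh and 0.09 for actin, went from -0.05 in the control to 0.28 with both treatments for the transferrin receptor, and for pyruvate carboxylase was smaller with both (2.19) than in the control (2.81). The hybridisation spike-ins were lower with both treatments as well (9.015 against 9.43 in the control). How far the arrays differed in signal before deposit therefore stays open too. A joint effect of MAL and Med23 loss, which the design names, is also open. With 1 array per condition it cannot be told apart from the amount of RNA or the signal of the arrays.

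Cdkn2a and Cdkn2b read at most 3.59 on the KO arrays, below the lowest KO array median of 3.86, and at least 9.34 on the WT arrays. The 5 nearest tested genes on each side had a median coefficient of -0.245, with Mtap at -0.01 and Tusc1 at -0.20. Caap1 fell by 1.10 on the log2 scale (adjusted p = 0.00351). Among these neighbours are the interferon genes Ifnab, Ifnz and Ifna1, and a gene with little RNA in WT cells could not fall. The levels of the neighbours were not weighed, so their median argues against loss of a wider segment only where they are expressed. A candidate explanation is loss or silencing limited to these genes in the KO line, which immortalised spontaneously. RNA levels alone cannot separate loss from silencing, nor say whether either came before or after the loss of Med23, so the highest KO level of 3.59 leaves this open.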

How the results depend on the processing

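All alternatives were planned except the fits without probe sets whose names end in _s_at or _x_at, which were chosen after seeing the data. For the changes given here the cause was not tested, except that fits on fewer arrays have fewer residual degrees of freedom. Arrays were paired by serum time in the MEFs and by the other treatment in the 10T1/2 cells, and the labels give no replicate numbers for a further block. The pseudocount alternative was not run, because the deposited values are log2 values. The number of arrays limits the fits, and genes near the array medians are limited by their signal over background. For KO against WT the count was 2857 without a term for serum time, 1948 with a bound of 1 on the absolute log2 change, and from 2398 to 4891 with 1 serum time left out. At 30 min of serum it was 13 with the mean of all probe sets, 59 with an intensity trend, 58 in 1 fit over all arrays and 10 without the 90 min arrays. At 90 min it was 18 without the 30 min arrays and 822 with the bound of 1. For MAL the count of 8 became 587 with the mean of all probe sets, 0 without the filter, 5 with the filter at the 75th percentile, 853 after quantile normalization, 0 with centred arrays, 542 with the trend, 2236 in 1 fit over all arrays and 0 without the knockdown term, and for the knockdown the count of 0 became 340, 899, 599 and 2658 with the mean, quantile normalization, trend and joint fit.

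Over the named genes and their alternatives, direction and side of the threshold were kept in 861 results for KO against WT, with 40 losing the call and 5 gaining it, in 217 at 30 min (28 losing, 4 gaining), 316 at 90 min (32 losing), 196 for MAL (27 losing, 66 gaining) and 203 for the knockdown (88 gaining). Over all called list members, 103 of 223 lost the call for KO against WT in at least 1 run without a serum time, 10 of 16 at 30 min and 102 of 111 at 90 min. Values without a test moved as follows. The differences in serum response at 30 min numbered 129 with the stricter filter and 1068 with a bound of 1.5-fold, and at 90 min 2476 with that bound. With the mean of all probe sets, 678 genes lay 2-fold from the control with MAL, 516 with the knockdown, and 491 departed from additivity. At 1.5-fold these were 3220, 3051 and 2802, and 6552 with both treatments. The correlation between the 2 kinds of Med23 loss was 0.168 for 30 min and both treatments against MAL, 0.107 for 90 min and knockdown against control, and 0.0815 for 90 min and both treatments against MAL. With an estimated correlation 0 lists passed in each of the 5 comparisons, against 7, 10, 6, 7 and 4. That version has 2 degrees of freedom in the MEFs and 1 in the 10T1/2 cells. A list can hardly pass it, so this count does not tell how far the lists depend on correlation between genes. Among named genes, those that changed sign had coefficients near 0: after quantile normalization Mrtfa at 30 min (-0.0242), Med23 with MAL (0.0013) and Pparg with the knockdown (-0.0981), and Srf with MAL (0.0075 with the mean of all probe sets and 0.09 without _s_at and _x_at probe sets). Mrtfa with the knockdown had a coefficient of 0 in the main fit and so no sign to change. It stood at -0.0288 after quantile normalization and 0.02 with centred arrays.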

Other observations

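The test of the hypothesis given here was chosen only after the list medians had been seen. The response of S phase and mitosis genes was more positive in KO than in WT cells for 30 of 33 genes at 30 min, with a median difference of 0.36 above 100% of random lists, by values only. In 10T1/2 cells the array of both treatments stood below the control for bone and cartilage genes (median -1.12, above 0% of random lists) and for cholesterol synthesis genes (-0.75, above 0.88% of random lists), and the array with the knockdown alone stood below it for interferon-stimulated genes (-0.43, above 0% of random lists).

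A hypothesis from these lists is that loss of Med23 raises smooth muscle genes relative to immediate-early genes. The median change of the smooth muscle list lay above that of the immediate-early list in all 5 pairs of arrays with and without Med23, by 2.80, 2.18 and 1.75 in the MEFs at 0, 30 and 90 min, by 0.775 for the knockdown alone and by 1.09 for the knockdown beside MAL. It also did so in the 2 pairs with and without MAL, by 0.98 and 1.45. These are the pairs from which the hypothesis came, so they do not test it independently, and since the pairs with MAL show the same order, a part of Med23 cannot be told apart from a general shift toward contractile genes.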
